A study of Homo sapiens with 144 samples.

How the data were processed

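Gene expression was measured by RNA sequencing in VCaP prostate cancer cells sampled 0, 3, 6 and 12 h into a treatment course with dihydrotestosterone (DHT). The labels describe 144 samples in 2 sets, one called HT and one called time course. The HT set has 50 samples, each a numbered column with the cells of up to 40 chambers, and the time-course set has 94 libraries, of which 90 are single cells and 4 are bulk populations. Per the labels, libraries were made with the Nextera XT kit, which keeps no strand, so antisense and overlapping genes could not be told apart. The labels state that cells were moved to medium with charcoal-stripped serum 1 day before treatment, stained with 1 of 2 cell tracker dyes, and given ethanol or DHT. Which cells received which dye or ethanol was not given in the sources used here.

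Both deposited tables hold FPKM per gene and cell, per the labels, and the values carried decimals, were never negative and differed in their sum from cell to cell. The authors aligned reads with TopHat2 2.0.6 to hg19 (GRCh37), per the labels. The FPKM tool, the gene annotation and any filter on cells were not given in the sources used here. Coordinates are those in the HT table (hg19, first base numbered 1), and no coordinate of a genome on GRCh38 was used. The tables share 57424 genes. Of the gene entries for HT cells, 217 shared their identifier with another entry. In gene lists, shares of cells and the search for outlying columns, a name shared by several identifiers stood for the identifier with the highest mean. The largest rises and falls were ranked by identifier. A name such as Y_RNA or snoU13 among them need not be the identifier used in that search. The time-course table had 14 missing values, which were left out of means.

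The HT table holds 39 columns with 1453 cells: 10 columns each at 0, 6 and 12 h and 9 at 3 h, where column 7 had no values. The labels list a second set of 10 columns at 0 h. The table names 1 set of 0 h columns, which was matched to the first set by time and column number, and the second set was not analysed here. Which run the values at 0 h came from is not stated beyond this match. The 12 h titles and those of the matched 0 h columns carry lane 1, and the 3 and 6 h titles and the second 0 h set lane 2, so lane and time were confounded in comparisons of 3 or 6 h with 0 h. Column numbers ran from 1 to 10 at 0 and 3 h and from 11 to 20 at 6 and 12 h. Column number and time were therefore confounded in comparisons of 6 or 12 h with 0 h and of 6 with 3 h. Nothing in the labels says that columns came from separate cultures, so p-values measure only the spread between columns, which may be technical. Each time-course cell is a sample of its own with no culture named, so each time point counted as 1 sample and no test between times was made there. The bulk populations are 1 library per time.

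FPKM gives no read counts. Relative depth per cell was therefore estimated from the value that 1 read gives to genes near the floor, over 6918 genes in the HT set and 15187 in the time-course set. Of these low values, 44.9% (HT) and 48.0% (time course) lay near a step, not all steps being whole, against 29.4% if spread evenly. The fit itself centres the values of a cell on a step, so part of this excess is built in. Depth is therefore approximate. Median relative depth of HT cells was 3.39 at 0 h, 0.901 at 3 h, 0.789 at 6 h and 1.08 at 12 h. In the time-course cells it was 1.14, 0.842, 0.882 and 1.14. A gene listed at 0 in a cell may be expressed below what its reads could show.

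For the HT set, cells with 500 or more genes above 0 FPKM were kept. FPKM was averaged over the kept cells of each column, and log2(mean + 1) was compared between times with linear models in limma 3.58.1 (R 4.3.3) with a mean-variance trend and 1 fit over the 4 times. Genes with a mean of at least 1 FPKM over columns were tested (14710), and p-values were adjusted by the Benjamini-Hochberg method, with adjusted p under 0.05 as the threshold. Count models were not used because the tables hold no counts. Comparisons were 12, 6 and 3 h with 0 h, and 6 with 3 h. Gene lists with at least 5 tested members were compared with all other genes by camera (preset correlation 0.01), and again with the correlation estimated from the data. The other genes were not matched to a list in mean level. The numbers of members past the threshold are given after adjustment over all genes and, in brackets, after adjustment over the list alone. The share of cells with at least 1 FPKM was taken per column for 9 genes and compared by permutation of columns, exact with the 9 columns at 3 h and with 100000 random permutations otherwise.

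In the time-course set all 90 cells passed the filter of 1000 genes at 1 FPKM or more. At 0 h, 2 of the libraries held identical values for all genes and were counted as 1 cell, which left 89 cells. Mean FPKM over cells was compared between times as log2(mean + 1), and the bulk populations in the same way. The median change of a list was placed among 10000 random lists of genes matched in mean level. Shares of cells carry exact binomial 95% intervals, which show counting error only. Changes were compared between sets by Spearman and Pearson correlation across genes, where genes are not replicates and no p-value is given.

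The 19 lists were written before the data were examined: androgen induced, androgen repressed, ERG associated, S phase, G2/M phase, immediate early, heat shock, unfolded protein response, cholesterol and fatty acid synthesis, polyamine synthesis, hypoxia and glycolysis, interferon response, neuroendocrine, prostate luminal, basal, stromal, immune, mitochondrially encoded and housekeeping genes. The same holds for the rule for naming genes. In each HT comparison with 0 h it took the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 FPKM in the higher group. In the time-course set it took the 10 largest rises and falls at 12 h among genes detected in at least 25% of cells at either time, with a mean of at least 5 FPKM in the higher group and the same direction in bulk. In each comparison it added members of these 2 androgen lists and ERG that passed, and 7 genes in any case, KLK3, KLK2, TMPRSS2, FKBP5 and ERG among them. It also added up to 4 members of each other list by smallest adjusted p. In the time-course set, with no p-values, the largest change at 12 h was used for those members instead. For length, the text names part of the androgen list members that passed and part of the other list members. Some genes that the rule took are not reported here. VCaP is 1 cell line, so no group of cells was named as a cell type. A list of 15 genes of estrogen-receptor-positive breast cells was written later, after 7 of them had been seen.

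Alternatives tried were pseudocounts of 0.1 and 5, no filter on low values or a mean of 5 FPKM, all cells or cells with at least 1500, 3000 (time course) or 4500 genes, means of log2 values, cells rescaled to the same sum, quantile normalization, a fit of 2 groups only, a replicate block by column number (3 h with 0 h), an estimated correlation for lists, at least a 2-fold change, detection above 0 or at 10 FPKM, leaving out 1 unusual cell, and counting the identical 0 h libraries as 2 cells. The cells with 4500 or more genes, weighted by their number per column, were added after the spread of gene numbers had been seen. Other groupings of the same columns (100 splits per comparison) were counted. The models were tested on simulated data. Each value was drawn from a normal distribution around the gene's mean over all columns, with its SD within times, independently for each gene. Then 200 of 14710 genes were given a set change, and the calls were counted. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.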

Results

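VCaP prostate cancer cells were sampled at 0, 3, 6 and 12 h of treatment with DHT, the active form of testosterone, in 2 sets of single-cell libraries. The HT set gave 1453 cells in 39 columns: 373 at 0 h, 338 at 3 h, 369 at 6 h and 373 at 12 h. The time-course set gave 21, 23, 22 and 23 single cells and 1 bulk population per time. A further 0 h library held the same values as another for every gene, and these were counted as 1 cell. VCaP carries the TMPRSS2-ERG fusion, which puts the transcription factor ERG under the control of an androgen-driven promoter. DHT was therefore followed through androgen-induced genes, ERG and the growth and stress programs that androgen is known to reach.

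Cells in the HT set differed strongly in quality between times. Median genes above 0 FPKM per cell were 627 at 0 h, 3469 at 3 h, 6204 at 6 h and 5752 at 12 h, and mitochondrial genes took a median of 86.1%, 36.2%, 9.13% and 7.23% of FPKM. High mitochondrial shares with few genes are a usual mark of damaged cells or nearly empty chambers. Cells with at least 4500 genes are called high-gene cells here. They made up 15.3% of cells at 0 h (57 cells), 17.5% at 3 h (59), 80.8% at 6 h (298) and 81.0% at 12 h (302). The low shares were thus those of columns 1 to 10 (0 and 3 h) and the high ones those of columns 11 to 20 (6 and 12 h). Column number cannot be told apart from time in this. In high-gene cells the median mitochondrial share was 8.12%, 11.1%, 8.34% and 6.66%. Changes below are over cells with 500 or more genes unless high-gene cells or quantile normalization are named.

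**Figure D1:**
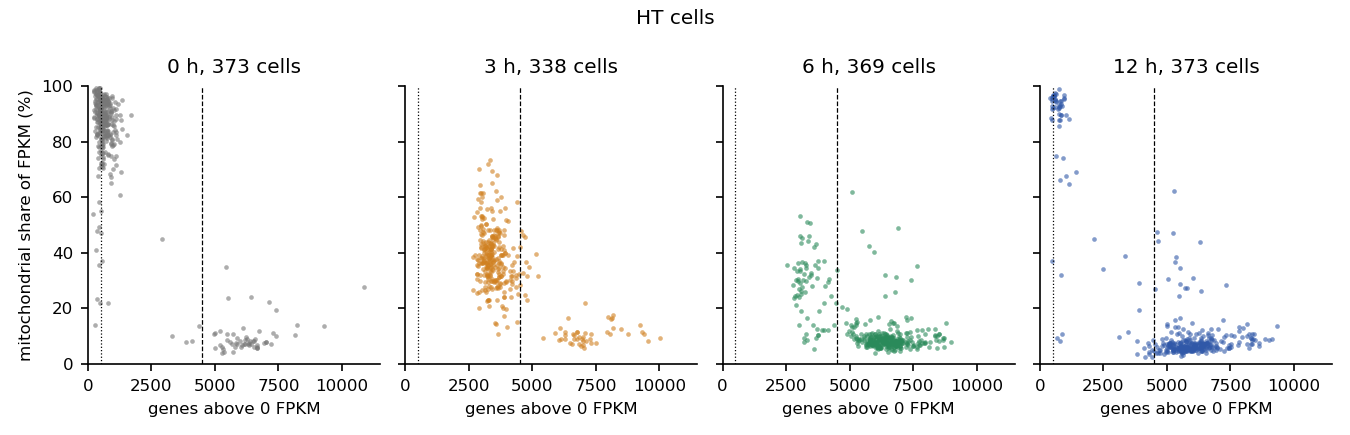
Genes above 0 FPKM (x axis) and mitochondrial share of FPKM (y axis) for each cell of the HT set, 1 panel per time. Cells at 0 h lay mostly at few genes and high mitochondrial share.

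After 12 h of DHT, the hormone has had time to change both its direct target genes and the pathways these feed. Androgen induces prostate genes such as KLK3 (prostate-specific antigen), KLK2 and TMPRSS2, and FKBP5, a cochaperone. It also drives lipid synthesis and secretory capacity. The 12 h columns and the 0 h columns matched to the values shared a lane number in their titles. Their column numbers did not overlap (11 to 20 and 1 to 10), so column number and time were confounded here.

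Of 14710 genes tested with limma (10 columns against 10), 10594 were higher and 75 lower at 12 h, with a median log2 change over all genes of 1.60. The split depended on the cells kept and on scaling: it was 2285 higher and 192 lower in high-gene cells (median 0.51), and 1611 higher and 1579 lower after quantile normalization (50.5% of calls higher, median -0.05). Of 10661 and 2437 genes called in the full and high-gene comparisons, among 14457 tested in both, 2282 were called in both in the same direction and 51 in opposite directions. Changes of single genes below are therefore best read against the median of all genes, which itself differed with mean level. Over genes with a mean of at least 5 FPKM it was 2.10 at 12 h, 1.65 at 3 h and 2.35 at 6 h, each against 0 h. The list tests of the HT set were not matched on mean level, so passing them need not mean a rise above genes of like level.

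Androgen-induced genes were higher as a list. FKBP5 (ENSG00000096060.10, hg19 chromosome 6, 35541362 to 35696360) rose from 0.733 ± 1.23 to 284 ± 32.7 FPKM (mean ± SD over columns), a log2 change of 7.56 ± 0.25 (SE, adjusted p = 6.96e-25), with 6.84 in high-gene cells. ACSL3 (ENSG00000123983.9, hg19 chromosome 2, 223725652 to 223809357), which activates fatty acids, rose from 20.02 ± 35.99 to 501 ± 114 FPKM (5.46 ± 0.39, adjusted p = 1.65e-14). KLK3 (ENSG00000142515.10, hg19 chromosome 19, 51358171 to 51364020) rose from 0.232 ± 0.415 to 8.94 ± 2.74 FPKM (3.02 ± 0.24, adjusted p = 3.35e-13). The change was nearly the same in high-gene cells (2.96). TMPRSS2 (ENSG00000184012.7, hg19 chromosome 21, 42836478 to 42903043) rose from 2.13 ± 2.42 to 35.9 ± 19.6 FPKM (3.76 ± 0.36) and by 2.38 in high-gene cells. KLK2 (ENSG00000167751.8, hg19 chromosome 19, 51364824 to 51383823) rose by 3.21, but by 1.05 in high-gene cells. EAF2 (5.00, then 4.75 in high-gene cells), STEAP4 (4.26, then 3.35) and SLC45A3 (3.41, then 2.27) rose as well. So did PMEPA1 (4.02, then 2.25), MPHOSPH9 (4.81, then 3.66) and NDRG1 (3.99, then 1.89). NCAPD3, a condensin subunit (ENSG00000151503.8, hg19 chromosome 11, 134020014 to 134095348), rose by 7.005, from 7.86 ± 10.4 to 570.5 ± 123 FPKM. In the androgen-induced list 29 of 30 tested genes were higher (29 adjusted over the list alone), with a median of 3.18, or 1.43 after quantile normalization. It passed the list test (camera adjusted p = 1.25e-12, and 0.0165 with an estimated correlation). In high-gene cells 24 were higher (26 over the list alone), with a median of 1.91.

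ERG moved with the induced genes. ERG (ENSG00000157554.14, hg19 chromosome 21, 39751949 to 40033704) rose from 5.86 ± 5.96 to 64.2 ± 11.4 FPKM (3.61 ± 0.36, adjusted p = 4.17e-11) and by 2.07 in high-gene cells (adjusted p = 4.04e-05). This is the direction an androgen-driven fusion would give. Androgen-repressed genes depended on the cells kept: 4 of 8 (4 over the list alone) were higher over all kept cells, with a median of 0.88 (camera adjusted p = 0.103), which became -0.62 after quantile normalization. In high-gene cells 1 of 10 was higher and 3 lower (1 and 3), with a median of -0.41 (camera adjusted p = 0.00121). Its members CITED2 (2.94, and 1.73 in high-gene cells), DDC (1.96, then 0.41 and no longer past the threshold) and SESN1 (1.74, then 0.44, not past it, and -0.50 after quantile normalization) were higher over kept cells. The ERG-associated list had 6 of 8 genes higher (6), among them PLA1A (2.25, and 0.69 in high-gene cells, where it did not pass), with a median of 1.80 (-0.36 after quantile normalization) that did not differ from other genes (camera adjusted p = 0.545).

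**Figure D2:**
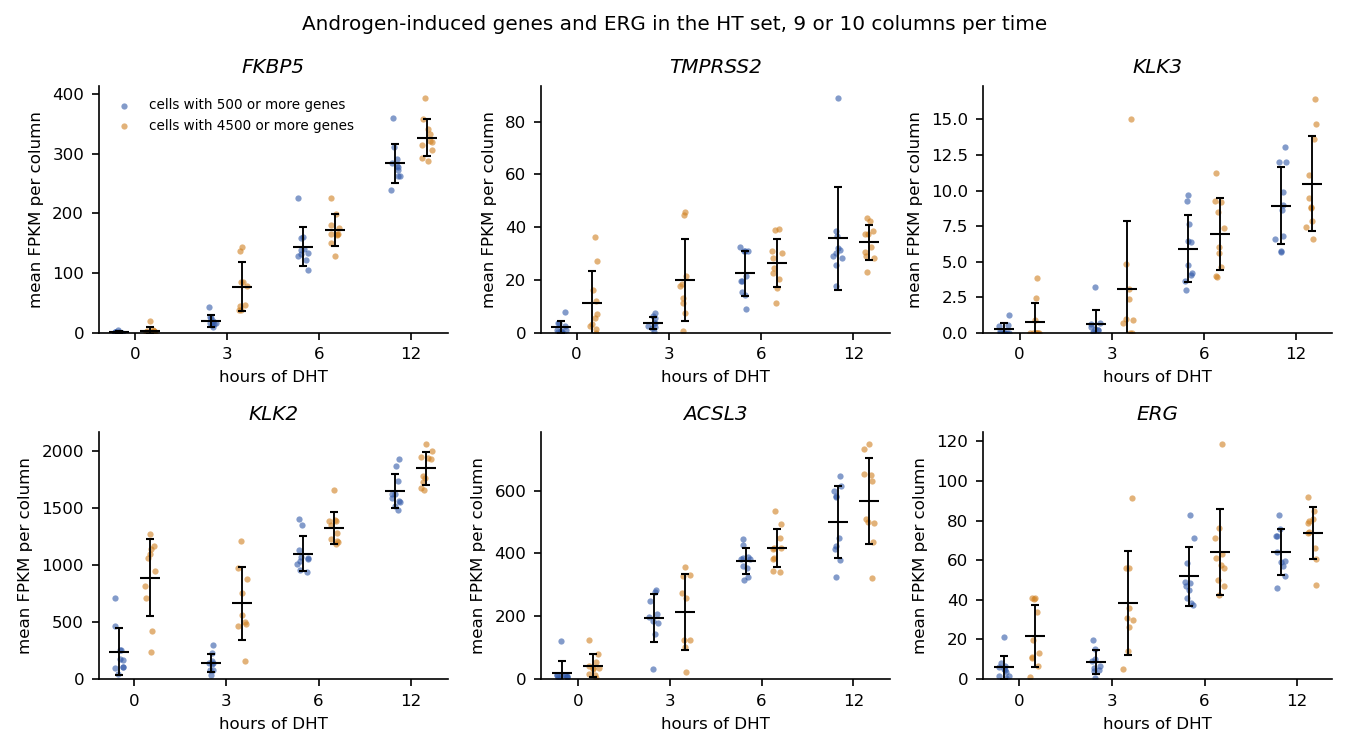
Mean FPKM per column at 0, 3, 6 and 12 h for 5 androgen-induced genes and ERG in the HT set, over cells with at least 500 genes (blue) and at least 4500 genes (orange). All 6 were higher at 12 h than at 0 h in both.

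Endoplasmic reticulum and lipid genes followed. All 17 tested genes of the unfolded protein response were higher (17 over the list alone), with a median of 4.07, 2.54 in high-gene cells and 2.01 after quantile normalization. This too passed the list test (camera adjusted p = 1.06e-12, and 0.0139 with an estimated correlation). DNAJB9, a chaperone cofactor of HSPA5 (ENSG00000128590.4, hg19 chromosome 7, 108210012 to 108215294), rose from 0.421 ± 0.564 to 61.8 ± 25.3 FPKM (5.43 ± 0.27, adjusted p = 3.74e-19). It was followed by SDF2L1 (4.89), TRIB3 (3.72) and HSPA5 itself (3.43, and 1.53 in high-gene cells). Of 22 cholesterol and fatty acid genes 21 were higher (21), with a median of 2.86, 1.37 in high-gene cells and 0.70 after quantile normalization (camera adjusted p = 6.03e-06, and 0.0251 with an estimated correlation). FDFT1 (3.95) and INSIG1 (3.03) led it. The polyamine list had 8 of 8 higher (8), with SMS at 3.45 and a median of 2.69 (camera adjusted p = 0.00759, but adjusted p = 0.239 with an estimated correlation). In high-gene cells 3 of 8 were higher, with a median of 0.83 (camera adjusted p = 0.098). For hypoxia and glycolysis 13 of 17 were higher (13), with a median of 2.05 that did not differ from other genes (camera adjusted p = 0.507). In high-gene cells 2 of 17 were higher (median 0.06), and after quantile normalization 2 were higher and 1 lower (median 0.19). VEGFA rose from 4.95 to 129 FPKM (4.88, and 3.98 in high-gene cells).

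Proliferation and stress lists mostly moved with the median of all genes. In S phase 26 of 47 genes were higher (26), with a median of 1.24 (-0.20 after quantile normalization, camera adjusted p = 0.0527). In G2/M phase 48 of 56 were higher (49), with a median of 2.12 (0.76 after quantile normalization, camera adjusted p = 0.239). High-gene cells had 3 higher and 2 lower of the former (median 0.34) and 8 higher of the latter (median 1.30, camera adjusted p = 0.0188, but 0.812 with an estimated correlation). FEN1 (3.28), ATAD2 (3.54), CKS1B (3.81) and AURKA (3.79) passed over kept and in high-gene cells. Immediate early genes had 12 of 18 higher and 1 lower (12 and 1), with a median of 1.38, but -0.50 after quantile normalization. In high-gene cells 0 of 19 were higher and 4 lower (0 and 7), with a median of -0.35 (camera adjusted p = 4.74e-08). Accordingly JUND (2.07, then -0.03), KLF6 (2.36, then -0.12) and ATF3 (2.58, then 0.34) passed over kept cells and not in high-gene cells. Heat shock genes were higher in 11 of 12 (11), with a median of 2.01 (camera adjusted p = 0.0558). In high-gene cells 2 of 12 were higher (median 0.36) and HSP90AB1 went from 2.06 to -0.08, and after quantile normalization 0 of 12 were higher (median 0.17). Interferon genes were higher in 7 of 9 (7), with a median of 1.38 (camera adjusted p = 0.97) and ISG15 at 3.25, against 1 of 10 and 0.81 in high-gene cells. Neuroendocrine genes were higher in 6 of 7 (6), with a median of 2.02 (-0.10 after quantile normalization, camera adjusted p = 0.545) and SCG2 at 3.20, against 1 of 8 and 0.16 in high-gene cells.

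Lineage and control genes differed between the settings too. Luminal genes were higher in 10 of 12 (10), with a median of 2.15 and 0.04 after quantile normalization (camera adjusted p = 0.0918), and in high-gene cells 4 were higher and 3 lower (median 0.31). AMACR (4.19, and 3.14 in high-gene cells) and KRT18 (2.99, then 1.20) led them. Too few genes of the basal (2 of 2 higher, KRT15 at 2.42), stromal (1 of 2, FN1 at 1.17, then 0.15, and -0.69 after quantile normalization) and immune (1 of 1, LCP1 at 2.41, then 0.30) lists were tested for a list test. Housekeeping genes were higher in 12 of 12 (12), with a median of 2.11, against 0.31 in high-gene cells and 0.23 after quantile normalization (camera adjusted p = 3.70e-04, but adjusted p = 0.283 with an estimated correlation). GAPDH went from 2.39 to 0.35 in high-gene cells, where it did not pass (adjusted p = 0.181), and YWHAZ from 2.72 to 0.84. Mitochondrially encoded genes were lower in 12 of 13 and higher in 1 (12 and 1), with a median of -2.56 (camera adjusted p = 6.64e-60, and 2.16e-05 with an estimated correlation). In high-gene cells their median was 0.31. MT-CO2 fell by 2.65 and MT-ND3 by 2.55, with 0.16 and -0.08 in high-gene cells.

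Small noncoding genes were prominent among the largest changes, where a few reads on a short gene give a high FPKM. Y_RNA (7.36), VTRNA1-3 (7.23), RNA5SP392 (6.98), MIR3661 (6.93), AC006483.1 (6.503), CTD-3141N22.1 (6.35) and snoU13 (5.97) rose, and RNU6-118P was listed at 0 at 0 h and at 268 FPKM at 12 h. Among the falls were SCARNA18 (-7.88), SNORA41 (-7.59), SNORD116-29 (-6.23, ENSG00000207245.1, hg19 chromosome 15, 25351668 to 25351750), SNORA36A (-6.17), SNORA21 (-6.04), SNORA34 (-5.87), SNORD116-2 (-5.72), SNORD116-6 (-5.16), SNORA73B (-5.12) and SNORD116-8 (-4.89). None of these 10 falls passed in high-gene cells, and copies of such genes in the genome are too alike to be sure which one was read.

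At 3 h of DHT mainly direct androgen targets with fast transcription can have changed, and FKBP5 is among the earliest. Repression tends to come later. Lane and time were confounded here, since all 3 h columns carried lane 2 and the 0 h columns matched to the values lane 1, so no change can be laid to DHT alone. With 9 columns against 10 in limma, 7368 genes were higher and 306 lower (median log2 change 1.00), against 1200 and 312 in high-gene cells (median 0.05) and 2871 and 3007 after quantile normalization (48.8% of calls higher, median -0.16). In high-gene cells and the full comparison 1305 genes were called in the same direction and 36 in opposite directions.

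Among androgen-induced genes, FKBP5 rose to 20.1 ± 10.3 FPKM (3.68 ± 0.26, adjusted p = 2.57e-15) and by 4.60 in high-gene cells. ACSL3 rose by 3.95 (2.34 in high-gene cells), EAF2 by 1.44 (2.75), SGK1 by 5.48 (4.65), CENPN by 7.38 (6.38) and PMEPA1 by 1.60 (1.28, and -0.41 after quantile normalization). KLK3 (0.30, adjusted p = 0.337), KLK2 (-0.52, 0.207), TMPRSS2 (0.69, 0.117) and ERG (0.56, 0.213; -1.23 after quantile normalization) did not pass. KLK4 (-1.09, adjusted p = 0.0116) and TRPM8 (-1.06, 0.0352) were lower, and neither passed in high-gene cells. As a list, androgen-induced genes had 13 of 30 higher and 2 lower (13 and 2), with a median of 0.72, and did not differ from other genes (camera adjusted p = 0.948). In high-gene cells 7 were higher (7, and 1 lower) and the list passed (camera adjusted p = 9.44e-04, and 0.0335 with an estimated correlation, median 0.35). After quantile normalization 4 were higher and 13 lower, with a median of -0.64. Androgen-repressed genes had 2 of 8 higher and 1 lower (2 and 3), with a median of -0.50 (camera adjusted p = 0.0387, but adjusted p = 0.203 with an estimated correlation). MET (3.05) and CITED2 (2.28) were higher and NOV lower (-1.42, and -2.93 in high-gene cells). In the ERG-associated list 1 of 8 was higher and 1 lower (1 and 1), the latter CRISP3 (-1.69, adjusted p = 0.00148). The list had a median of -0.15 (camera adjusted p = 0.0139, but adjusted p = 0.203 with an estimated correlation). In high-gene cells 2 of 9 were lower (median -0.74, camera adjusted p = 0.0122, and 0.0359 with an estimated correlation), and after quantile normalization 5 of 8 were lower (median -1.30, camera adjusted p = 8.96e-04, and 0.00436 with an estimated correlation).

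None of the 10 largest rises at 3 h was in the androgen-induced list. TFF1, an estrogen-induced secreted peptide (ENSG00000160182.2, hg19 chromosome 21, 43782391 to 43786703), rose from 2.60 ± 5.63 to 18920 ± 1536 FPKM (13.40 ± 0.63, adjusted p = 9.08e-21). LGALS1 (931 FPKM), C3orf14 (881), HSPB1 (782; ENSG00000106211.8, hg19 chromosome 7, 75931861 to 75933612), DSCAM-AS1 (749; ENSG00000235123.1, hg19 chromosome 21, 41755010 to 41757285) and GATA3 (344; ENSG00000107485.11, hg19 chromosome 10, 8095567 to 8117161) were listed at 0 in all 10 columns at 0 h. UBE2C (10.01), MSMB (9.21), S100P (9.17) and VTRNA1-3 (8.40) made up the rest of the 10 largest rises. Each of these 10 was also higher in high-gene cells. Falls were led by SNORD116-29 (-5.87), SNORD116-6 (-5.84), RNU4-46P (-5.12), SNORA5A (-5.06), SNORA27 (-4.45), SNORA79 (-4.19), SNORA66 (-4.09), SNORD89 (-4.07), SNORA11 (-3.86) and SNORA4 (-3.84). None of these passed in high-gene cells, where SNORA66 was too low to be tested.

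Cell cycle genes were higher at 3 h as a whole. All 47 S phase genes were higher (47), with a median of 3.54, 2.41 in high-gene cells and 2.58 after quantile normalization (camera adjusted p = 8.31e-16, and 5.91e-05 with an estimated correlation). All 56 G2/M genes were higher (56), with a median of 4.34 (2.76 in high-gene cells, 2.82 after quantile normalization, camera adjusted p = 4.86e-17, and 0.0327 with an estimated correlation). CKS2 (ENSG00000123975.4, hg19 chromosome 9, 91926113 to 91931618) rose from 7.30 ± 8.58 to 1082 ± 268 FPKM (7.62 ± 0.44), with AURKA at 7.01, GINS2 at 6.20 and RRM2 at 5.95. Luminal keratins moved with them: KRT19 (ENSG00000171345.9, hg19 chromosome 17, 39679869 to 39684560) rose by 7.12, KRT8 by 4.39 and KRT18 by 4.30. The luminal list had 8 of 12 higher and 4 lower (8 and 4), with a median of 2.51 (camera adjusted p = 0.56).

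Stress and metabolic lists at 3 h were weaker. Heat shock genes were higher in 12 of 12 (12), with HSPD1 at 3.68 and a median of 2.79 (camera adjusted p = 4.19e-07, and 0.0327 with an estimated correlation). In the unfolded protein response 16 of 17 were higher (17), with XBP1 at 3.88 and a median of 1.55, but 0.00 after quantile normalization (camera adjusted p = 0.0055, but adjusted p = 0.309 with an estimated correlation). Cholesterol and fatty acid genes were higher in 17 of 22 (19), with SCD at 3.65 and a median of 2.37 (camera adjusted p = 0.0011, but adjusted p = 0.128 with an estimated correlation), and after quantile normalization they did not differ from other genes (median 0.58, camera adjusted p = 0.114). Polyamine (7 of 8 higher, median 2.26, camera adjusted p = 0.111) and hypoxia (11 higher and 1 lower of 17, median 1.97, ALDOA at 4.60, camera adjusted p = 0.0692) genes did not differ from other genes. The same was found for immediate early (13 of 18 higher, median 1.19, but -0.79 in high-gene cells and -0.70 after quantile normalization, camera adjusted p = 0.894), interferon (4 of 9 higher, median 0.52, but -0.24 after quantile normalization, camera adjusted p = 0.948) and neuroendocrine lists (1 of 7 higher, median -0.13, camera adjusted p = 0.0966). High-gene cells had medians of 0.71 for heat shock (5 of 12 higher), 0.60 for the unfolded protein response (3 of 17), 0.89 for cholesterol and fatty acid (5 of 22), 0.37 for polyamine (2 higher and 1 lower of 8) and 0.51 for hypoxia genes (6 higher and 1 lower of 17, camera adjusted p = 0.0181, but 0.0544 with an estimated correlation). There immediate early genes were lower relative to other genes (camera adjusted p = 6.63e-04, but 0.0681 with an estimated correlation). Basal (2 of 2 higher), stromal (1 of 2 higher) and immune (1 of 1 lower) genes were too few for a test. Housekeeping genes were higher in 12 of 12 (12), with ACTB at 3.79, GAPDH at 2.57 and a median of 1.78, against 0.31 in high-gene cells and -0.16 after quantile normalization (camera adjusted p = 2.93e-04, but adjusted p = 0.203 with an estimated correlation). Mitochondrial genes were lower in 11 of 13 and higher in 1 (11 and 1), MT-ND6 (2.38), with a median of -0.87 (camera adjusted p = 7.28e-11, but adjusted p = 0.0926 with an estimated correlation). In high-gene cells all 13 were higher (median 1.94), and MT-ND3 turned from -1.04 to 1.26.

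By 6 h, slower androgen targets should have joined the early ones, and the secretory response should follow. Lane was again confounded with time, since 6 h columns carried lane 2. Column number was as well (11 to 20 at 6 h, 1 to 10 at 0 h). Comparing 10 columns with 10 in limma, 11556 genes were higher and 70 lower than at 0 h (median 1.78), against 3130 and 186 in high-gene cells (median 0.62) and 2084 and 2258 after quantile normalization (48.0% of calls higher, median -0.06). High-gene cells and the full comparison shared 3113 calls in the same direction and 66 in opposite directions.

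FKBP5 rose to 144 ± 32.6 FPKM (6.57 ± 0.25, adjusted p = 1.27e-23), KLK3 to 5.90 ± 2.35 (2.47 ± 0.24, adjusted p = 2.33e-11), TMPRSS2 to 22.4 ± 8.42 (3.13 ± 0.36, adjusted p = 7.28e-10) and ERG to 51.9 ± 14.9 (3.28 ± 0.36, adjusted p = 2.28e-10), each also higher in high-gene cells (5.92, 2.45, 1.98 and 1.82). KLK2 rose by 2.63 (0.57 in high-gene cells). ACSL3 (5.08), EAF2 (4.95), STEAP4 (3.82; ENSG00000127954.8, hg19 chromosome 7, 87905744 to 87936206) and CENPN (6.72) also rose. All 30 androgen-induced genes were higher (30), with a median of 2.92, 1.74 in high-gene cells and 0.62 after quantile normalization (camera adjusted p = 1.21e-08, but adjusted p = 0.0573 with an estimated correlation, and 5.96e-06 in high-gene cells). Among androgen-repressed genes 5 of 8 were higher (4), with a median of 1.08 (-0.08 in high-gene cells, -0.92 after quantile normalization, camera adjusted p = 0.133, but 0.00907 in high-gene cells, and 0.0261 there with an estimated correlation): CITED2 (2.63), DDC (2.47), MET (1.97), and SESN1 (1.01, but -0.29 in high-gene cells and -1.42 after quantile normalization). The ERG-associated list had 7 of 8 higher (7), with a median of 1.83 (-0.39 after quantile normalization, camera adjusted p = 0.661).

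The transcripts that led the rises at 3 h were high at 6 h too. TFF1 was at 10140 ± 1355 FPKM (12.49 ± 0.61), LGALS1 at 531, C3orf14 at 478, DSCAM-AS1 at 356 and HSPB1 at 317, with UBE2C (8.98), MSMB (8.39), S100P (8.33), Y_RNA (7.92) and VTRNA1-3 (7.73) completing the 10 largest rises. S phase (47 of 47 higher, 47 over the list alone, median 3.41, camera adjusted p = 9.86e-09, and 0.00273 with an estimated correlation) and G2/M phase (56 of 56, 56, median 3.84, camera adjusted p = 4.13e-09, but adjusted p = 0.103 with an estimated correlation) had medians of 2.199 and 2.64 in high-gene cells and 1.46 and 2.01 after quantile normalization. CKS2 (7.06), CKS1B (5.66), GINS2 (5.33), RRM2 (4.91) and KRT19 (6.496) were among these rises. Falls were led by SNORD116-2 (-8.11), SNORA34 (-6.66), SCARNA18 (-6.66), SNORA36A (-6.43), SNORA4 (-6.15), SNORA21 (-5.49) and SNORA49 (-5.41), while SNORD116-29 (2779 FPKM at 0 h), SNORA41 (702) and SNORD116-8 (2122) were listed at 0. None of these 10 passed in high-gene cells.

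**Figure D3:**
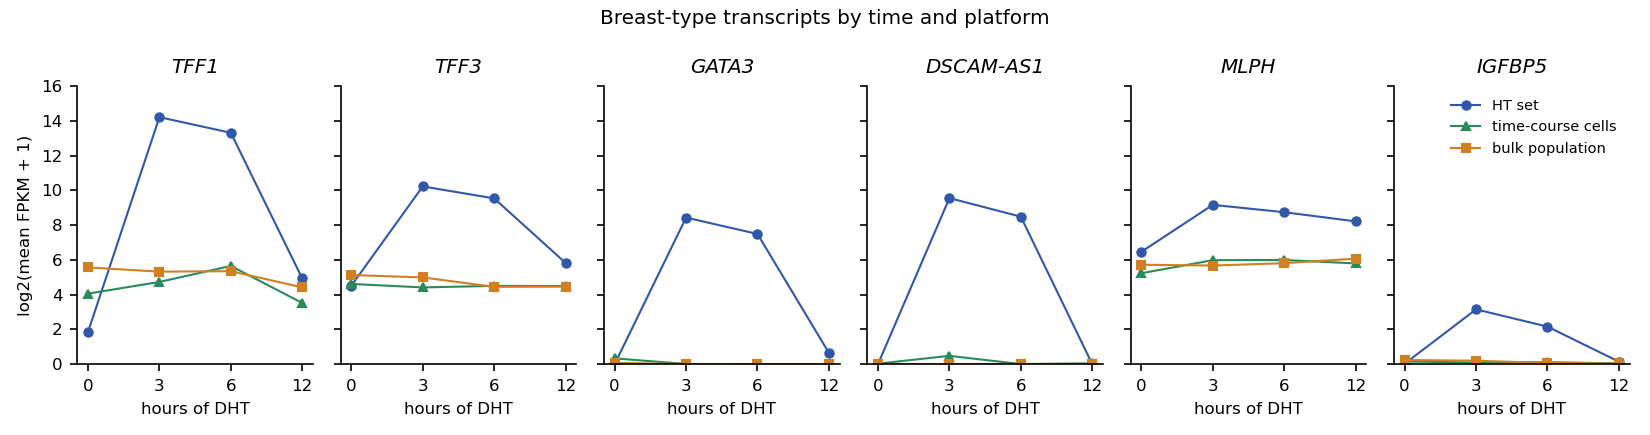
Mean level, as log2(mean FPKM + 1), of TFF1, TFF3, GATA3, DSCAM-AS1, MLPH and IGFBP5 at 0, 3, 6 and 12 h in the HT set (circles), the time-course cells (triangles) and the bulk populations (squares). All 6 were highest at 3 h in the HT set, and in the other sets none had a peak of that size.

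Protein folding and heat shock lists were higher at 6 h. All 17 genes of the unfolded protein response were higher (17), with a median of 3.50, 1.76 in high-gene cells and 1.25 after quantile normalization (camera adjusted p = 1.83e-07, but adjusted p = 0.0573 with an estimated correlation, and 0.00161 in high-gene cells). Members included DNAJB9 at 4.87, TRIB3 at 3.33 and HSPA5 at 2.97. Cholesterol and fatty acid genes were higher in 21 of 22 (21), FDFT1 at 3.73, with a median of 2.63 (camera adjusted p = 3.06e-04, but adjusted p = 0.0754 with an estimated correlation). After quantile normalization 5 of 22 were higher and 2 lower, and the list did not differ from other genes (median 0.29, camera adjusted p = 0.165, and 0.269 with an estimated correlation). Heat shock genes were higher in 12 of 12, with a median of 2.55 (camera adjusted p = 8.01e-06, but adjusted p = 0.0573 with an estimated correlation). With an estimated correlation this list passed in high-gene cells (adjusted p = 0.00951) and after quantile normalization (median 0.34, adjusted p = 8.53e-04). The polyamine (8 of 8, median 2.82, camera adjusted p = 0.0316, but adjusted p = 0.285 with an estimated correlation) and luminal lists (9 of 12, median 2.78, camera adjusted p = 0.0316, but adjusted p = 0.348 with an estimated correlation) were less certain, and neither passed in high-gene cells (camera adjusted p = 0.41 and 0.516) or after quantile normalization (0.261 and 0.124). Immediate early (17 of 18, median 1.71, but -0.57 after quantile normalization, camera adjusted p = 0.231) and hypoxia (13 of 17, median 2.35, but -0.11 after quantile normalization, camera adjusted p = 0.231) genes did not differ from other genes. Neither did interferon (8 of 9, median 2.25, camera adjusted p = 0.562) and neuroendocrine genes (7 of 7, median 1.72, but -0.78 after quantile normalization, camera adjusted p = 0.562). In high-gene cells medians were 1.20 for cholesterol and fatty acid (11 of 22 higher), 0.89 for heat shock (5 of 12), 0.71 for polyamine (4 of 8), 0.96 for luminal (6 higher and 4 lower of 12), -0.16 for immediate early (2 and 2 of 19, camera adjusted p = 0.00116, but 0.109 with an estimated correlation), 0.52 for hypoxia (5 of 17), 1.45 for interferon (2 of 10) and 0.19 for neuroendocrine genes (3 of 8). Basal (2 of 2 higher), stromal (1 of 2) and immune (1 of 1) genes were not tested as lists. Housekeeping genes were higher in 12 of 12 (12), GAPDH at 2.55, with a median of 2.37, against 0.38 in high-gene cells (camera adjusted p = 1.11e-04, but adjusted p = 0.179 with an estimated correlation). Mitochondrial genes were lower in 12 of 13 and higher in 1 (12 and 1), with a median of -2.72 (camera adjusted p = 3.18e-63, and 1.32e-05 with an estimated correlation) but 0.89 in high-gene cells, and MT-CO2 turned from -2.79 to 0.69.

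Between 3 and 6 h both groups shared lane 2, so lane did not differ in this comparison. Column numbers did (1 to 10 at 3 h, 11 to 20 at 6 h). The mix of chambers differed too: those under 4500 genes made up 82.5% of cells at 3 h and 19.2% at 6 h. In limma GATA3 was lower at 6 h (344 and 178 FPKM, adjusted p = 0.00432), and TFF1 went from 18920 to 10140 FPKM without passing (adjusted p = 0.297). A rise of androgen-induced genes over kept cells therefore cannot be laid to DHT alone. FKBP5 can be induced within hours. With 10 columns against 9 in limma, 3780 genes were higher and 231 lower at 6 h (median 0.57), against 612 and 38 in high-gene cells (median 0.45) and 933 and 857 after quantile normalization (52.1% of calls higher, median -0.03). Kept and high-gene cells shared 574 calls, all in the same direction.

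KLK2 rose from 143 ± 78.8 to 1100.0 ± 155 FPKM (3.14 ± 0.34, adjusted p = 4.38e-09, and 1.10 in high-gene cells), FKBP5 by 2.89 (1.32), KLK3 by 2.17 (1.43), STEAP4 by 3.32 (2.10), EAF2 by 3.51 (1.94) and NDRG1 by 3.50 (1.52). TMPRSS2 (2.44) and ERG (2.73) rose over kept cells but did not pass in high-gene cells (0.79 and 0.80, adjusted p = 0.305 and 0.196). SGK1 fell by 2.15 (adjusted p = 0.00401), though it did not pass in high-gene cells (-1.80, adjusted p = 0.196). In the androgen-induced list 25 of 30 were higher and 1 lower (27 and 1), with a median of 2.26, 1.01 in high-gene cells and 1.57 after quantile normalization (camera adjusted p = 3.43e-17, and 0.00328 with an estimated correlation). ERG-associated genes were higher in 6 of 8 (8), CRISP3 at 3.35, with a median of 1.73 (camera adjusted p = 5.48e-05, and 0.0381 with an estimated correlation). Androgen-repressed genes were higher in 4 of 8 (4), with a median of 1.30 (camera adjusted p = 0.374).

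Genes of protein folding rose between 3 and 6 h: DNAJB9 by 3.96 ± 0.27 (adjusted p = 2.09e-13, and 3.81 in high-gene cells), ATF4 by 1.75 and HSPA5 by 1.73. The unfolded protein response had 11 of 17 higher (11), with a median of 1.30 (camera adjusted p = 2.14e-04, but adjusted p = 0.16 with an estimated correlation). S phase (4 lower of 47, 2 over the list alone, median -0.43, camera adjusted p = 3.46e-12, and 2.95e-04 with an estimated correlation) and G2/M phase (2 lower of 56, 1, median -0.59, camera adjusted p = 2.26e-13, but adjusted p = 0.0515 with an estimated correlation) were lower relative to other genes. In high-gene cells 0 of 47 and 0 of 56 were lower, with medians of -0.09 and -0.14. Their members GINS2 (-0.87), RRM2 (-1.04) and HN1 (-1.14) were lower over kept cells but not past the threshold in high-gene cells. HSPB1 fell by 1.35, within a heat shock list (1 lower of 12, 1) with a median of -0.14, which was 0.11 with cells rescaled to the same sum (camera adjusted p = 0.00166, but adjusted p = 0.155 with an estimated correlation). Neuroendocrine genes were higher in 5 of 7 and lower in 1 (6 and 1), with a median of 2.23 (camera adjusted p = 0.00977, but adjusted p = 0.155 with an estimated correlation). Immediate early (6 of 18 higher, median 0.68, camera adjusted p = 0.281), cholesterol (4 higher and 1 lower of 22, median 0.30, but -0.27 after quantile normalization, camera adjusted p = 0.441) and polyamine (2 of 8, median 0.52, camera adjusted p = 0.643) genes did not differ from other genes. Hypoxia genes (2 of 17, median 0.07, but -0.19 after quantile normalization) did not differ over kept cells (camera adjusted p = 0.143), but in high-gene cells they were lower relative to other genes (1 lower of 17, camera adjusted p = 4.23e-04, and 0.00691 with an estimated correlation). No difference from other genes was found for interferon (4 of 9, median 1.04, camera adjusted p = 0.572), luminal (5 of 12, ACPP at 2.82, median 0.38, camera adjusted p = 0.511) and housekeeping lists (3 of 12, median 0.32, but -0.02 after quantile normalization, camera adjusted p = 0.613). In high-gene cells medians were 0.80 for the unfolded protein response (7 of 17 higher), 0.59 for neuroendocrine (2 of 8) and between -0.05 (hypoxia) and 0.95 (interferon) for heat shock, immediate early, cholesterol, polyamine, luminal and housekeeping genes and these 2. Basal (1 lower of 2), stromal (0 of 2) and immune (1 higher of 1) genes were too few. Mitochondrial genes were lower in 12 of 13 (12), MT-CO2 by -1.96, with a median of -1.88, and -1.11 in high-gene cells (camera adjusted p = 1.84e-42, and 2.95e-04 with an estimated correlation).

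A mean can rise because more cells respond or because each cell responds more. The share of cells with at least 1 FPKM was compared between columns. It cannot separate these 2, since a share also rises with the level in each cell and with cell quality. Which cells received ethanol was not given, so a share need not be that of DHT-treated cells. KLK3 was detected in 2.59 ± 4.69% of cells at 0 h and in 41.2 ± 11.1% at 12 h, and FKBP5 in 4.15% and 95.6%, with 4.71% and 58.7% at 3 h. TMPRSS2 went from 11.9% to 72.2%, SLC45A3 from 12.0% to 82.2%, ERG from 14.01% to 81.1% and KLK2 from 64.6% to 100%. ACTB, a control, went from 38.6% to 89.6%, so higher shares were not limited to androgen-induced genes. Of 36 comparisons 30 passed by permutation, with 1e-05 the smallest p that 100000 permutations can give. At 3 h against 0 h KLK3 (adjusted p = 0.302), TMPRSS2 (0.324), SLC45A3 (0.329) and ERG (0.0721), all by exact permutation, were among those that did not. In high-gene cells 19 passed: there KLK3 went from 9.50% to 48.1% of cells at 12 h, FKBP5 from 18.8% to 99.7%, TMPRSS2 from 52.2% to 81.9% and ERG from 53.7% to 91.2%. These are means over columns, which held only 2 to 13 high-gene cells each at 0 h. Their SD over columns at 0 h was 17.1 points for KLK3, 18.9 for FKBP5, 28.9 for TMPRSS2 and 14.4 for ERG.

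The time-course set followed the same treatment in fewer cells with more genes each, together with a bulk population per time. Median genes at 1 FPKM or more per cell were 8969, 7926, 7935.5 and 8939, and mitochondrial genes took 17.1%, 12.9%, 10.9% and 19.2% of FPKM (13.2%, 8.84%, 8.64% and 21.8% in bulk). Without MT-TL1, a gene of 75 bases, these shares were 9.69%, 9.57%, 9.52% and 8.84% (8.82%, 8.84%, 8.64% and 7.91% in bulk). Each time counted as 1 sample, so values are given without a test, and intervals show counting error only. FKBP5 went from 5.365 to 162, 287 and 358 FPKM at 3, 6 and 12 h (21.6, 499, 861 and 1403 in bulk), ERG from 20.2 to 79.6, 101 and 129 (17.1, 74.6, 74.6 and 91.3) and TMPRSS2 from 4.76 to 31.99, 35.5 and 37.6, most of it by 3 h, when TMPRSS2 had not passed in the HT set. KLK3 stayed between 12.3 and 30.6 FPKM in cells, seen in 57.1%, 47.8%, 59.1% and 56.5% of them, and went from 14.6 to 31.8 in bulk, while KLK2 (706.6 to 944) was high at all times.

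The largest changes at 12 h were ranked without a test. ORM2 (ENSG00000228278.2, hg19 chromosome 9, 117092149 to 117095532), a secreted plasma glycoprotein, went from 0.0342 to 85.4 FPKM (0 to 108 in bulk), from 0 of 21 to 22 of 23 cells (95.7%, 95% interval 78.1 to 99.9). The other large rises were NCAPD3 (18.5 to 469.9, 25.4-fold), STEAP4 (0.912 to 55.0), TUBA3D (0.653 to 61.8), TBX15 (0.00358 to 20.4), RNU5E-1 (6.12 to 148), and RNY3P8 (51.2) and RP3-340B19.5 (26.4), both listed at 0 at 0 h. SHH, the hedgehog ligand (ENSG00000164690.3, hg19 chromosome 7, 155592680 to 155604967), went from 236 to 11.1, 0.107 and 1.43 FPKM (156, 23.7, 3.51 and 0.593 in bulk), from 17 of 21 to 3 of 23 cells. MYC (ENSG00000136997.10, hg19 chromosome 8, 128747680 to 128753674) went from 118 to 22.6, 5.11 and 3.11 FPKM. FOLH1, which encodes prostate-specific membrane antigen (ENSG00000086205.12, hg19 chromosome 11, 49168187 to 49230222), went from 215 to 123, 36.8 and 9.02 FPKM, and lower values at 12 h were also found for IGFBP3 (72.7 to 1.58), PLA2G2A (62.01 to 1.996), REG4 (136.5 to 5.73), MID1 (33.35 to 0.770), SYTL2 (132 to 6.34), C11orf92 (80.46 to 4.08) and RP11-617J18.1 (30.5 to 0.127).

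The median change of the 31 measured androgen-induced genes was 1.04, 1.15 and 1.16 at 3, 6 and 12 h (1.04, 1.16 and 1.502 in bulk), above all 10000 random lists each time, with 17 members at least 2-fold higher at 12 h and 0 lower. Among its members EAF2 went from 14.3 to 186 FPKM and ACSL3 from 33.8 to 279.6. The 9 androgen-repressed genes went the other way (-0.54, -1.15 and -1.70; -0.55, -1.08 and -2.26 in bulk; percentiles 2.825, 0.155 and 0), with OPRK1 (17.1 to 1.20), UGT2B15 (6.76 to 0.231), HSD17B6 (13.3 to 1.20) and AKR1C3 (31.5 to 7.90), but CITED2 was higher (1.08 to 5.71). The unfolded protein response (0.67, 1.36 and 1.44; percentiles 99.7, 100 and 100) and lipid synthesis (0.34, 0.62 and 1.30; percentiles 87.4, 99.4 and 100) were higher, the latter later. S phase genes had medians of 0.11, -0.38 and -0.62 (percentiles 65.6, 2.165 and 0.02), with PRIM1 (17.1 to 1.39) and MCM2 (6.42 to 0.189) lower but FEN1 higher (0.0493 to 8.12). G2/M genes had medians of -0.17, -0.40 and -0.31 (percentiles 7.435, 1.005 and 3.73), with TTK (10.3 to 0.613) and CCNB2 (9.24 to 0.727) lower at 12 h. ERG-associated genes were at 0.04, -0.27 and -0.44, the last at percentile 4.25. Immediate early genes were at -0.74, -0.20 and 0.43, and interferon genes at -0.97, -0.43 and 0.35. In single cells, medians at 12 h were 0.48 for hypoxia (percentile 96.95), 0.28 for heat shock, 0.38 for polyamine, 0.09 for neuroendocrine, -0.01 for luminal, 0.04 for housekeeping and -0.26 for mitochondrial genes. None of the last 6 lay above 95% of random lists or below as many in single cells. In bulk at 12 h, luminal genes did lie below as many (-0.42, percentile 2.485) and polyamine genes above (0.46, percentile 95.36), while hypoxia genes did not (percentile 93.4). Basal, stromal and immune lists had under 5 measured members.

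**Figure D4:**
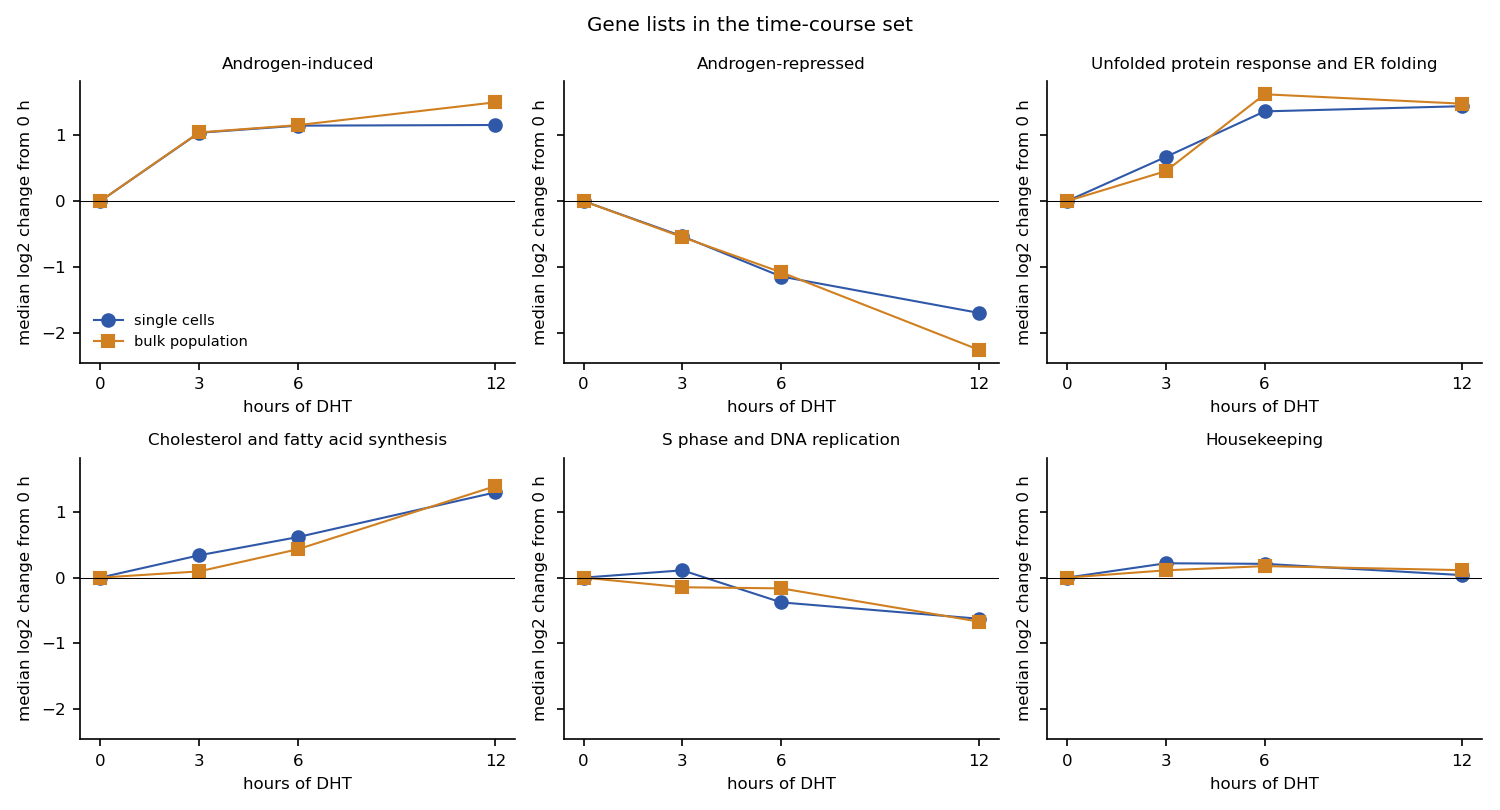
Median log2 change against 0 h of 6 gene lists in single cells (circles) and bulk populations (squares) of the time-course set. Androgen-induced, protein folding and lipid genes were higher and androgen-repressed genes lower at 12 h in both.

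Changes were compared across genes between the sets. At 12 h the Spearman correlation of HT and time-course changes was 0.284 over 14710 genes (Pearson 0.2555) and 0.3402 with high-gene cells, and at 3 and 6 h it was 0.0974 and 0.1996. Time-course cells and bulk gave 0.449 at 12 h. Of genes called higher at 12 h in the HT set 55.5% were above 0 in the time-course cells, where 48.9% of all genes were above 0, and with high-gene cells the share was 79.5%.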

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

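Single columns that lay apart from the rest of their time were sought in the HT set by Dixon's gap test on the scale of the model, a scale picked after the untransformed values had also been tried. Of 283 groups of 9 or 10 columns, 44 had such a column, where chance flags about 1 in 20 groups (14.2 here). They were uneven over time: 23 at 0 h, 8 at 3 h, 4 at 6 h and 9 at 12 h. Column 1 at 0 h had 7 of them, and no column was left out for this reason.

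At 0 h, column 1 was high in KLK3 (1.27 FPKM), STEAP4 (6.55), ACSL3 (121.8), AURKA (12.9) and SCG2 (11.4), and low in MT-CO2 (93630) and SNORA49 (0). Column 6 was high in FKBP5 (4.02), SGK1 (0.190) and CTD-3141N22.1 (38.1), and column 5 in RNA5SP392 (178), FN1 (4.38) and MSMB (0.895) and low in SNORA4 (16.6). Column 3 was high in SESN1 (29.8) and KRT15 (1.61), column 9 in S100P (49.3), and column 10 in FEN1 (0.874) and GINS2 (0.445) and low in SNORD116-2 (606). Low values were found for SNORA73B (14.5) in column 4, SNORA34 (0) in column 8 and SNORA79 (0) in column 2.

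At 3 h, column 8 was high in KLK3 (3.18), column 10 in SNORA66 (42.6) and column 5 in SNORD116-6 (598) and ACTB (747), while column 5 was low in ACSL3 (32.4) and CENPN (96.9). Column 1 had the fewest cells, 34, and 34 with at least 500 genes. At 6 h, column 12 was low in TFF1 (7204) and LGALS1 (234.5) and had 39 high-gene cells, and column 19 was low in ATF4 (134). At 12 h, column 20 was high in TMPRSS2 (89.1) and SCARNA18 (729), column 14 in SESN1 (53.2), column 18 in VEGFA (308) and column 16 in SNORD116-8 (1375). Column 15 was low in snoU13 (0), column 18 in SNORA21 (0), column 12 in FEN1 (2.18) and column 16 in AMACR (22.6).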

How the results depend on the processing

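Which settings changed a result was counted over 18 main results with 176 alternatives, of which 129 gave the same answer, 45 moved (a count by over 1.5 times, or a value without a test in its second decimal), 1 was stronger and 1 weaker. For 219 single genes or shares of cells, those reported here, 2225 alternatives gave the same answer in 1988 cases, weaker in 136, reversed in 44, moved in 48 and stronger in 9. The comparison of high-gene cells (at least 4500 genes, weighted by cells), the runs without single unusual cells and the count of identical libraries as 2 cells were chosen only after results had been seen. The second set of 0 h columns was not analysed here, so neither its comparison with the first set nor its use as control was run. Except where a paragraph says so, the cause was not tested. Changes are log2 unless named as counts or shares.

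Cells with 1500 or more genes gave 4394 higher and 182 lower genes at 12 h, 3438 and 2046 at 3 h, and 5189 and 271 at 6 h. Directions reversed at 12 h for SNORD116-29 (1.999), SNORA36A (1.44), SNORD116-2 (1.35), SNORD116-6 (1.73) and SNORA73B (1.30). At 3 h they did for SNORD116-29 (2.34), SNORD116-6 (1.03), SNORA5A (0.68), SNORA66 (0.076), SNORA4 (0.61), PMEPA1 (-0.44), ERG (-1.37) and MT-ND3 (2.2), and at 6 h for SNORA36A (1.497), SNORA49 (0.59), SESN1 (-0.57) and MT-CO2 (0.70). Shares of cells turned at 3 h for TMPRSS2 (-32.7 points), SLC45A3 (-41.3) and ERG (-29.0).

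High-gene cells gave 2285 higher and 192 lower genes at 12 h, 1200 higher at 3 h, 3130 and 186 at 6 h, and 612 and 38 for 6 against 3 h. The androgen-induced list at 3 h passed here and in no other setting run (mean 1.01, camera adjusted p = 9.44e-04). Reversed at 12 h were SNORD116-29 (0.95), SNORA36A (0.25), SNORD116-2 (1.87), SNORD116-6 (1.86), SNORA73B (0.20), JUND (-0.027), KLF6 (-0.12), HSP90AB1 (-0.076) and MT-CO2 (0.16). At 3 h these were SNORA5A (0.38) and MT-ND3 (1.26), and at 6 h SNORD116-2 (0.080), SNORA36A (0.018), SNORA49 (0.28), SESN1 (-0.29) and MT-CO2 (0.69). The shares passing went from 30 to 19, and turned at 3 h for KLK2 (-1.06 points). Correlation of HT with time-course changes at 12 h went from 0.284 to 0.3402.

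Quantile normalization gave 1611 higher and 1579 lower genes at 12 h, 2871 and 3007 at 3 h, 2084 and 2258 at 6 h, and 933 and 857 for 6 against 3 h. It reversed SESN1 (-0.50) and FN1 (-0.69) at 12 h, PMEPA1 (-0.41) and ERG (-1.23) at 3 h, and SESN1 (-1.42) at 6 h.

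Genes lower at 3 h numbered 200 with all cells, 166 with means of log2 values and 193 with a fit of the 2 groups only. For 6 against 3 h, higher genes were 2270 at a mean of at least 5 FPKM and 8954 with means of log2 values, and lower genes were 124 with a pseudocount of 0.1, 380 with 5, 146 with cells rescaled to the same sum and 406 with a fit of the 2 groups only. With an estimated correlation the androgen-induced list at 6 h no longer passed (mean 3.13, adjusted p = 0.0573). None of these counts tells which genes were called.

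In the time-course set means of log2 values moved the androgen-induced medians to 1.094, 1.093 and 1.39 at 3, 6 and 12 h, and turned KLK3 to 0.25 at 6 h and 0.21 at 12 h. A pseudocount of 0.1 moved these medians to 1.17, 1.168 and 1.24, and to 1.58 in bulk at 12 h. Leaving out the 6 h cell with the highest MT-TL1 moved the 6 h median to 1.21, and leaving out the 3 h cell of lowest depth moved the 3 h median to 1.092. With the identical 0 h libraries counted as 2 cells the medians were 1.06, 1.19 and 1.196. Over genes with a mean of at least 5 FPKM in both sets the correlation at 12 h was 0.4299.

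With column number as a replicate block, 3 against 0 h gave 5895 higher and 211 lower genes, and 46 gene results were the same and 5 weaker. Correlations between columns of the same number were -0.028 to 0.052 over 9 pairs, and 1 column was closest to its own number, so the numbers pair no samples.

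On simulated data with 14710 genes, 200 of them changed (50 per size), changes of 1, 2, 3 and -2 were found for 7, 36, 46 and 41 of 50 genes in the 12 h comparison, for 7, 39, 48 and 34 at 3 h, for 14, 35, 48 and 38 at 6 h, and for 9, 35, 45 and 37 for 6 against 3 h. Unchanged genes called were 9, 5, 8 and 4. Of 16 lists, 1 was shifted, and the list test called that 1 in each comparison. Simulated genes were independent and equally spread at all times, so correlated genes and unequal spread between times were not covered.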

Other observations

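The genes of this paragraph, the depth, housekeeping and lane tests, the test of a DHT response of breast-type transcripts, the prostate sets and the other groupings of columns below were chosen only after the results were seen. In the time-course set some responses peaked early. SGK1, a kinase induced by steroid hormones, went from 4.88 to 25.3 FPKM at 3 h and 6.49 and 6.13 at 6 and 12 h (1.59, 30.3, 16.4 and 14.4 in bulk), and in the HT set it fell between 3 and 6 h. ZBTB16 went from 6.84 to 78.6, 81.9 and 60.6 FPKM and MAF from 0.778 to 10.3, 11.8 and 17.1. SESN1, a stress sensor, dipped from 16.6 to 3.77 and came back to 5.74 and 8.03 (20.1, 5.29, 7.96 and 7.39 in bulk), as did the Wnt receptor FZD4 (15.75, 2.59, 4.87 and 8.24; 15.3, 3.08, 4.59 and 9.37 in bulk). NCALD (19.6 to 2.79) and ARHGDIB (22.2 to 3.76), both ERG-associated, were lower at 12 h while ERG was higher.

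Most genes were higher at 12 h than at 0 h in the HT set. Fewer reads per cell in total at 0 h were argued against, since the median relative depth, as estimated, was at 0 h 3.14 times that at 12 h. This does not cover column 1 at 0 h, with a median of 0.875. Medians of the other 0 h columns ran from 2.13 to 6.16, and those at 12 h from 0.945 to 1.32. This depth does not set mitochondrial reads apart, and mitochondrial genes took a median of 86.1% of FPKM at 0 h and 7.23% at 12 h. Fewer reads left for other genes at 0 h therefore stay open. A response of most genes to DHT, in FPKM, was argued against as well: over the same genes the larger of the median changes in time-course cells and bulk was 0. Of these genes 48.9% had a change above 0 in time-course cells and 43.6% in bulk. FPKM is relative to the total of a library, so a rise in total RNA per cell would not show. Low-gene, mitochondria-rich chambers at 0 h stay open as a cause. The housekeeping median went from 2.11 over kept cells to 0.31 in high-gene cells, but a filter on gene number would lower it whatever the cause, so this decides nothing. A loss of cells without androgen stays open too, as does a difference between columns 1 to 10 (0 h) and 11 to 20 (12 h).

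Transcripts such as TFF1, TFF3, GATA3 and DSCAM-AS1 were at 18920, 1194, 344 and 749 FPKM at 3 h in the HT set, and at 10140, 740.1, 178 and 356 at 6 h, but at 29.4, 55.5, 0.564 and 0 at 12 h. Of 15 markers, 9 were higher at 3 h than at 12 h. Over kept cells, the HT log2 change of each at 3 h exceeded its largest change in time-course cells and bulk at 3 or 6 h. The median shortfall was 4.07 (range 1.94 to 10.8, SD 3.33). In high-gene cells, however, MLPH went only from 343.8 to 423.7 FPKM at 3 h, and GREB1 from 8.56 to 46.5. At 0, 3 and 6 h time-course cells had 36.45, 62.0 and 62.6 FPKM of MLPH (51.6, 49.9 and 55.0 in bulk). For GREB1 they had 11.9, 21.9 and 52.7 (11.9, 23.4 and 22.8 in bulk). A response to DHT was therefore argued against for the rest of the 9, and stays open for GREB1 and MLPH. AGR3 was not among the 9 (21.1 against 12.97 FPKM, adjusted p = 0.0599) and was higher at 3 and 6 h in time-course cells too (1.93, 21.4 and 76.3 at 0, 3 and 6 h). RNA from an estrogen-receptor-positive breast cell stays open. The list was written after 7 markers had been seen high (largest p = 5.41e-05). Of the 8 others 2, IGFBP5 and MLPH, were higher at 3 h than at 12 h (adjusted p = 4.33e-05 each, exact permutation, with each of 9 columns above all 10), while CA12 (6.36 against 14.6) was not. The bound set before was 2 or fewer of the 8 against this source, and the count met it. Of the 8, 4 stayed under 2 FPKM at both times, which was no part of that bound and is itself an outcome that it counted. The 7 markers seen before went the other way, but they were listed because they were high. This source therefore stays open, with the count of new markers against it. Of the 15, 6 were at 1 FPKM or more in time-course cells at 0 h, with MLPH at 36.45, TFF3 at 23.4 and CA12 at 10.2, and no sort that would remove other cells is described. A difference between lanes cannot be told apart from time, since all 19 columns at 3 and 6 h carry lane 2, and foreign RNA from another source stays open too.

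Cell cycle genes were higher at 3 and 6 h in the HT set. A response to DHT was argued against: in time-course cells and bulk the S phase list never lay above percentile 65.6 of random lists at 3 or 6 h. The same foreign RNA or reads may be the source, since S phase and G2/M genes took more of the nonmitochondrial FPKM in chambers under 4500 genes in 8 of 9 columns at 3 h (11590 against 8062 with sums set equal, exact sign test p = 0.0391), as the breast markers did in 9 of 9 (24650 against 13680, p = 0.00391). A set of 4 prostate genes, among them ACPP of the luminal list and the androgen-induced KLK2, went the other way (101.5 against 1947, in 0 of 9 columns higher). The 12 genes of the luminal list did not pass (3663 against 3890, in 2 of 9, exact sign test p = 0.18). Cells of another cell cycle state among the damaged ones stay open, untested.

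In each comparison 1 of 100 splits of the same columns, the real one, gave as many genes, so a chance order of the columns was argued against. Chance between cultures stays open, since columns are not known to be separate cultures. The real and highest other numbers were 10669 and 7322 at 12 h, 7674 and 4644 at 3 h, 11626 and 6302 at 6 h, and 4011 and 141 for 6 against 3 h.

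One time-course cell at 6 h had 5940000 FPKM of MT-TL1, a gene of 75 bases, where the next highest cell had 1664000 and the median was 0. Another, at 3 h, had a relative depth of 0.0141 and 3084 genes at 1 FPKM or more. Cells 18 and 21 at 3 h were low in depth too (0.0920 and 0.138) and were left out in no run. At 0, 6 and 12 h the lowest depths were 0.930, 0.507 and 0.739.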
